A study of Homo sapiens with 11 samples.

How the data were processed

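Polyadenylated RNA was measured by RNA-seq in 11 libraries of hTERT-HM cells, a human myometrial smooth muscle line immortalised with telomerase, grown as engineered myometrial microtissues. Libraries were taken on day 1 (n = 3), day 3 (n = 4) and day 6 (n = 4) of tissue formation, and the titles of the deposited samples gave each library its day. Per the labels' protocols, messenger RNA was captured on oligo-dT beads, fragmented by heat and reverse transcribed with random hexamers. The authors deposited counts of reads per gene, with no normalization, as 1 column per library, and none of the columns was left out (0 unused). Per the submitters' processing notes the build was GRCh38, and the tools named, with no role given, were DRAGEN, STAR 2.7.11b, Subread with featureCounts 2.0.8 and Salmon 1.10.0. Annotation release, strand setting and treatment of multi-mapping reads are not recorded there, so counts of overlapping genes, antisense genes and near-identical paralogs are uncertain. The table held 79031 rows, of which 92 spike-in and 7 transgene rows named no human gene. These rows held at most 2 counts in a library, at most 6.79e-06% of its total, and were left out of library sizes and tests.

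Library totals ranged from 28.07 to 33.02 M counts. A count of 3, taken as the limit that a count of 0 allows, corresponded to 0.0908 to 0.107 CPM (counts scaled to 1e6 per library); such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Genes were kept by the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15, by day), which left 18245 genes. The main test was edgeR's quasi-likelihood test with TMM factors and robust dispersion (R 4.3.3), with day as a factor and all 11 libraries in 1 fit. The contrasts were day 3 against day 1 (the early step), day 6 against day 3 (the late step), day 6 against day 1, and the late step minus the early step. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Means and SDs are of TMM-scaled CPM. The labels name replicates without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In a chi-square test over genes every pair of replicates differed beyond sampling noise, so no library was counted as a duplicate.

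The 34 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation and the fry test as alternatives. A further 8 lists were written after the data had been seen. Named genes were, for each comparison of 2 days, the 6 largest rises and the 6 largest falls among called protein-coding genes of at least 5 CPM on average whose libraries did not overlap between the days, up to 2 rising and 2 falling members of each list with the smallest adjusted p, and 10 genes named in every comparison (OXTR, ACTA2, CNN1, MYH11, TAGLN, MYLK, GJA1, PTGS2, COL1A1 and MKI67). For the late step minus the early step, 5 genes of either sign were taken whose day 3 libraries lay all above or all below the others. Values of 1 gene that these rules select are not reported here, and the gene stays in all counts and list tests.

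Alternatives were RLE factors, library totals only, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in at least 3 libraries, an added threshold of 1 on the absolute log2 fold change, a block for the replicate number or for the letter in the column names, a fit of only the 2 days compared, thinning to the smallest library, and leaving out each library in turn. The test was checked on 1 simulation with genes changed by known folds at the real means, library sizes and dispersions (17904 genes kept). In the comparison of days 3 and 6 it recovered 82.5% of genes changed 2-fold and 58.5% of those changed 1.5-fold, and 6.92% of its calls were false. For day 3 against day 1 these shares were 83.3%, 41.7% and 7.52%. For day 6 against day 1 they were 81.6%, 62.5% and 8.33%. The simulation changed 390 genes between days 3 and 6, far fewer than the 9102 called in the data. It also gave each gene the same dispersion on every day. These shares therefore need not hold for the real comparisons. Transcript length and GC content came from the longest transcript of each gene in GENCODE release 29, which matched 93.4% of the tested genes.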

Results

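RNA-seq libraries were compared over the 6-day formation of engineered myometrial microtissues, which the study built to measure contraction in response to oxytocin. The tissues were made from hTERT-HM cells, a telomerase-immortalised line of human myometrial smooth muscle. Day 1 had 3 libraries and days 3 and 6 had 4 each. The first principal component held 51.1% of the variance and set day 6 apart from days 1 and 3; the second held 12.4% and set day 1 apart from day 3.

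**Figure D1:**
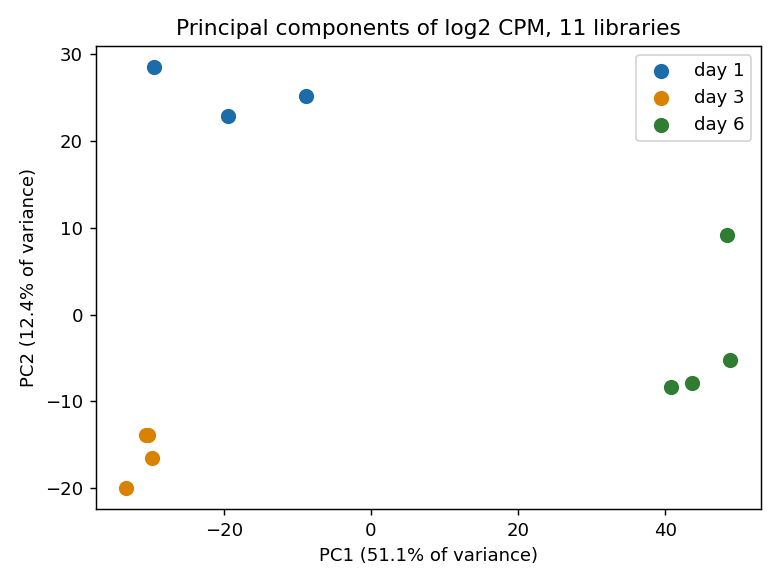
Principal components of log2 CPM, PC1 (51.1% of variance) on the horizontal and PC2 (12.4%) on the vertical axis, 1 point per library coloured by day. The 4 day 6 libraries lie at PC1 values from 40.75 to 48.8, and those of days 1 and 3 below -8.765 or at it.

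The day 3 against day 1 comparison asks what changed early in tissue formation. Leukaemia inhibitory factor (LIF), a cytokine of the interleukin 6 family, rose from 559.3 ± 60.3 to 1455 ± 136 CPM (SD, n = 3 and 4), and PTGES, which makes prostaglandin E2, rose from 12.79 ± 3.3 to 37.01 ± 3.23 CPM. The cationic amino acid transporter gene SLC7A2 rose most among the named genes, by 2.08 on the log2 scale (SE 0.266, adjusted p = 0.00164, edgeR), and the matrix metalloproteinase gene MMP10 by 1.57 (SE 0.366, adjusted p = 0.0248, edgeR). Expression of VIPR1, a receptor for vasoactive intestinal peptide, was 40.38 ± 15.9 CPM on day 1 and 6.923 ± 1.23 CPM on day 3, and RGS5, a regulator of G protein signalling, went from 180.4 ± 42.5 to 69.13 ± 6.04 CPM. Both falls were called, with log2 changes of -2.54 and -1.39.

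Of 27 tested inflammation genes, 11 rose and 1 fell (16 and 1 adjusted over the list alone), and the list was higher by camera (adjusted p = 5.35e-06 and adjusted p = 0.736 with an estimated correlation). ICAM1, a leukocyte adhesion molecule, rose from 163 ± 30.2 to 268 ± 14.8 CPM. Ribosomal protein genes rose in 33 of 36 cases (36 adjusted over the list alone), with a median log2 change of 0.28 (camera adjusted p = 4.07e-20 and adjusted p = 0.651 with an estimated correlation); RPLP0 went from 1412 ± 8.03 to 1946 ± 89.4 CPM. Of 14 heat shock genes 6 fell (9 adjusted over the list alone) and 0 rose (camera adjusted p = 1.63e-05 and adjusted p = 0.651 with an estimated correlation), among them HSPB8 and CRYAB, with log2 changes of -0.71 and -1.25. Among the 21 p53 targets 6 fell and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 0.00333 and adjusted p = 0.187 with an estimated correlation). Of the 13 mitochondrially encoded genes 4 fell (9 adjusted over the list alone, camera adjusted p = 0.00129 and adjusted p = 0.736 with an estimated correlation), and the share of counts on mitochondrial messenger RNA was 3.241% ± 0.244 on day 1 and 2.49% ± 0.202 on day 3 (exact permutation p = 0.0286, the smallest that 35 assignments allow; Benjamini-Hochberg adjusted 0.0429 over 9 tests).

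Immediate early genes were higher as a list, with 6 of 20 risen and 1 fallen (7 and 1 adjusted over the list alone, camera adjusted p = 0.0059 and adjusted p = 0.736 with an estimated correlation), EGR2 by 1.00. Contraction-associated genes rose in 5 of 19 cases (6 adjusted over the list alone, camera adjusted p = 0.0135 and adjusted p = 0.685 with an estimated correlation). Of 35 matrix genes 7 rose, COL3A1 by 0.87, and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0135 and adjusted p = 0.78 with an estimated correlation). Targets of TGF-beta rose in 9 of 25 cases and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0383 and adjusted p = 0.736 with an estimated correlation), BMP2 by 0.94. Hypoxia genes rose in 4 of 23 cases and fell in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0464 and adjusted p = 0.78 with an estimated correlation). The mitosis list was higher although 0 of its 34 genes were called, over all genes or adjusted over the list alone (camera adjusted p = 0.002 and adjusted p = 0.78 with an estimated correlation). The S phase list was higher with 2 of 35 risen (2 adjusted over the list alone, camera adjusted p = 0.0327 and adjusted p = 0.78 with an estimated correlation). The cholesterol list was lower with 1 of 23 fallen, INSIG1 (1 adjusted over the list alone, camera adjusted p = 0.0178 and adjusted p = 0.78 with an estimated correlation). The calls of the TGF-beta, S phase, hypoxia, cholesterol, matrix and mitosis lists ended with at least 1 library left out, the last at an adjusted p of 0.291 by camera without day 1 replicate 3.

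Contractile genes did not move as a list (camera adjusted p = 0.119 and adjusted p = 0.78 with an estimated correlation): 2 rose, 3 fell and 20 were not called (2 and 6 adjusted over the list alone). ACTA2, smooth muscle actin, rose by 0.61 (SE 0.136, adjusted p = 0.0142, edgeR), whereas MYOCD, a coactivator of smooth muscle genes, had a log2 change of -0.78 (SE 0.0822). The oxytocin receptor gene OXTR was at 5.647 ± 1.21 CPM on day 1 and 5.79 ± 0.553 CPM on day 3 (adjusted p = 0.918, edgeR). GJA1, the gap junction protein connexin 43, rose from 304.9 ± 11.6 to 508.7 ± 33.3 CPM. CNN1, TAGLN, MYLK, MYH11, COL1A1, MKI67 and PTGS2 were not called, with log2 changes of 0.21, 0.20, -0.29, -0.08, 0.23, 0.50 and 0.18. In all, 2332 of 18245 genes were called, 1255 higher and 1077 lower. The count was 1344 without day 1 replicate 1, 1352 without day 1 replicate 2 and 3617 with only these 2 days in the fit. Scaling by library totals called 840 higher and 1630 lower.

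The day 6 against day 3 comparison covers the late step. The smooth muscle genes rose: ACTA2 went from 63.45 ± 4.68 to 203.6 ± 14.1 CPM (n = 4 and 4), TAGLN from 299.7 ± 20.8 to 714.8 ± 83.8 CPM, CNN1, which encodes calponin, from 21.39 ± 1.81 to 56.72 ± 5.43 CPM, and MYLK, the myosin light chain kinase, from 21.22 ± 2.73 to 52.71 ± 5.26 CPM. Of 25 contractile genes 23 rose and 1 fell, SMTN, with a log2 change of -0.45 (23 and 1 adjusted over the list alone, camera adjusted p = 1.12e-08 and adjusted p = 0.539 with an estimated correlation). OXTR rose from 5.79 ± 0.553 to 8.85 ± 1.7 CPM (log2 change 0.61, SE 0.142, adjusted p = 0.00158, edgeR). Of 35 genes of the oxytocin and calcium list 15 rose and 8 fell, with a median log2 change of 0.08. Camera did not call the list (adjusted p = 0.763 and adjusted p = 0.919 with an estimated correlation), whereas fry called it higher (adjusted p = 0.0298). MYH11 and COL1A1 rose by 0.52 and 0.80. GJA1 went the other way, from 508.7 ± 33.3 to 383.3 ± 77.1 CPM (log2 change -0.41, SE 0.117, adjusted p = 0.0116, edgeR). Of 19 contraction-associated genes 8 fell and 3 rose (8 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0694 and adjusted p = 0.539 with an estimated correlation). The prostaglandin receptor gene PTGER3 fell, with -2.20, and PTGER4 rose, by 1.19. DES, which encodes desmin, had at most 2 counts in any library.

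**Figure D2:**
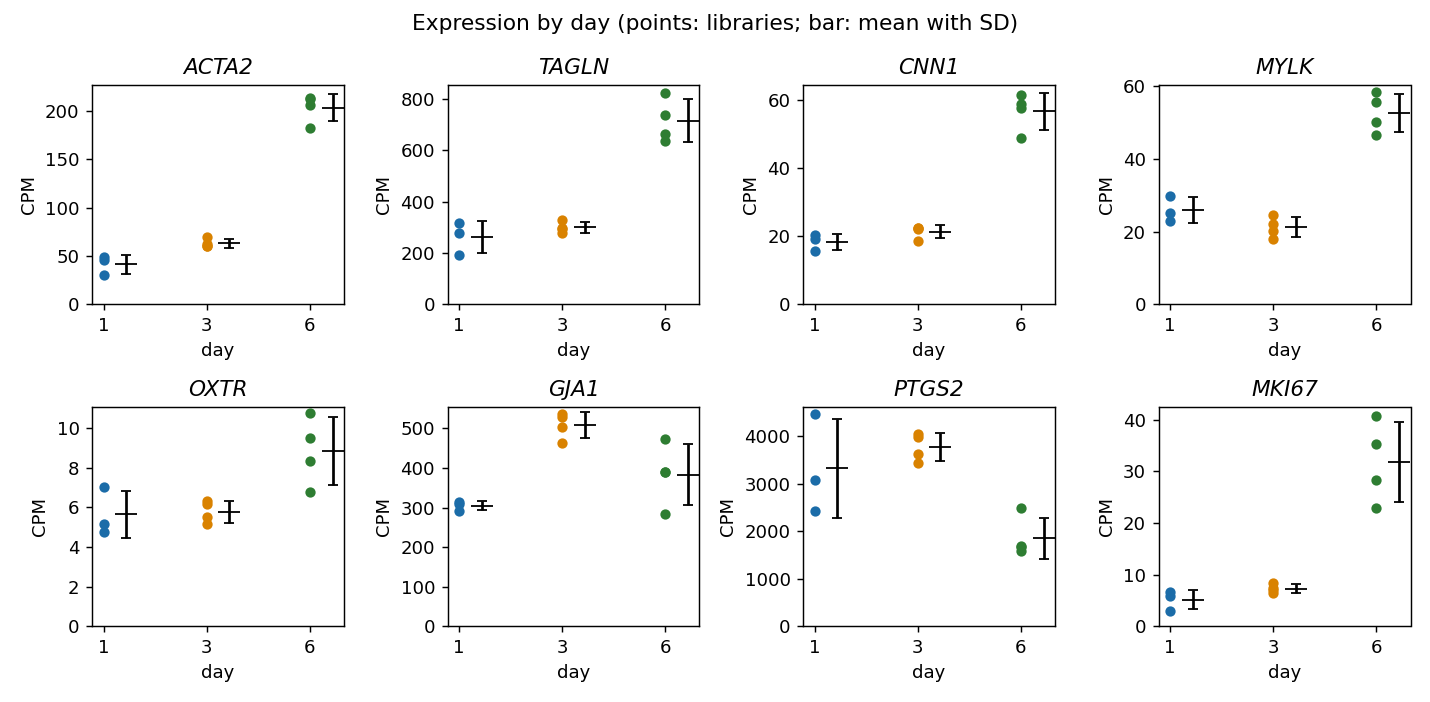
CPM (vertical axis, from 0) of 8 genes by day (horizontal axis); points are libraries and bars give the mean with its SD. ACTA2 was at 41.65 CPM on day 1 and 203.6 CPM on day 6, and MKI67 at 5.162 and 31.77 CPM.

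Cell cycle genes rose over the same step. All 34 tested mitosis genes and 33 of 35 S phase genes were higher (34 and 34 adjusted over the list alone), with median log2 changes of 1.76 and 0.95 (camera adjusted p = 9.44e-16 and 9.46e-11 and adjusted p = 0.539 for both with an estimated correlation). MKI67, a proliferation marker, went from 7.294 ± 0.842 to 31.77 ± 7.81 CPM and CENPF, a kinetochore protein, from 7.021 ± 0.977 to 33.76 ± 7.5 CPM. Of 23 cholesterol synthesis genes 20 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 1.78e-05 and adjusted p = 0.539 with an estimated correlation), SQLE among them. LSS was the one that fell, with a log2 change of -0.90. Of 21 targets of the YAP coactivator 13 rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.0255 and adjusted p = 0.539 with an estimated correlation). THBS1 and VCAN, which encode the matrix proteins thrombospondin 1 and versican, rose, the latter from 113.7 ± 9.03 to 448.1 ± 60 CPM. Of 35 matrix genes 15 rose and 9 fell, and the list was not called (camera adjusted p = 0.58 and adjusted p = 0.992 with an estimated correlation).

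Inflammation genes were lower in 20 of 27 cases and 2 rose (20 and 3 adjusted over the list alone), with a median log2 change of -1.06 (camera adjusted p = 2.77e-07 and adjusted p = 0.539 with an estimated correlation). ICAM1 went from 268 ± 14.8 to 50.48 ± 5 CPM and TNFAIP2 had a log2 change of -1.81. PTGES fell from 37.01 ± 3.23 to 1.343 ± 0.72 CPM, MMP1, interstitial collagenase, from 112.6 ± 17.9 to 11.8 ± 2.25 CPM, and PTGS2, cyclooxygenase 2, from 3775 ± 294 to 1856 ± 430 CPM. Of 24 endoplasmic reticulum stress genes 19 fell and 3 rose (19 and 3 adjusted over the list alone, camera adjusted p = 6.04e-07 and adjusted p = 0.539 with an estimated correlation), and of 23 hypoxia genes 18 fell and 2 rose (18 and 2 adjusted over the list alone, camera adjusted p = 0.000304 and adjusted p = 0.539 with an estimated correlation). VEGFA, a growth factor of blood vessels, was one of those that rose. Of 34 matrix remodelling genes 19 fell and 9 rose (20 and 9 adjusted over the list alone, camera adjusted p = 0.0408 and adjusted p = 0.806 with an estimated correlation), MMP13 with -1.68. All 36 ribosomal protein genes fell (36 adjusted over the list alone, median -0.54, camera adjusted p = 1.03e-18 and adjusted p = 0.539 with an estimated correlation).

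In the late step 9102 genes were called, 4825 higher and 4277 lower. With library totals only, which moved the median of all genes by 0.184 on the log2 scale, 7885 were higher and 2239 lower. The directions given for the lists in the late step were the same under TMM, RLE and library-total scaling. Camera called 10 of 34 lists. At least as many were called in 12 of the 35 splits of the 8 libraries, the real one included. The others that did so kept most libraries of each day together and still held part of the day difference. The splits therefore cannot decide whether chance gives as many list calls.

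**Figure D3:**
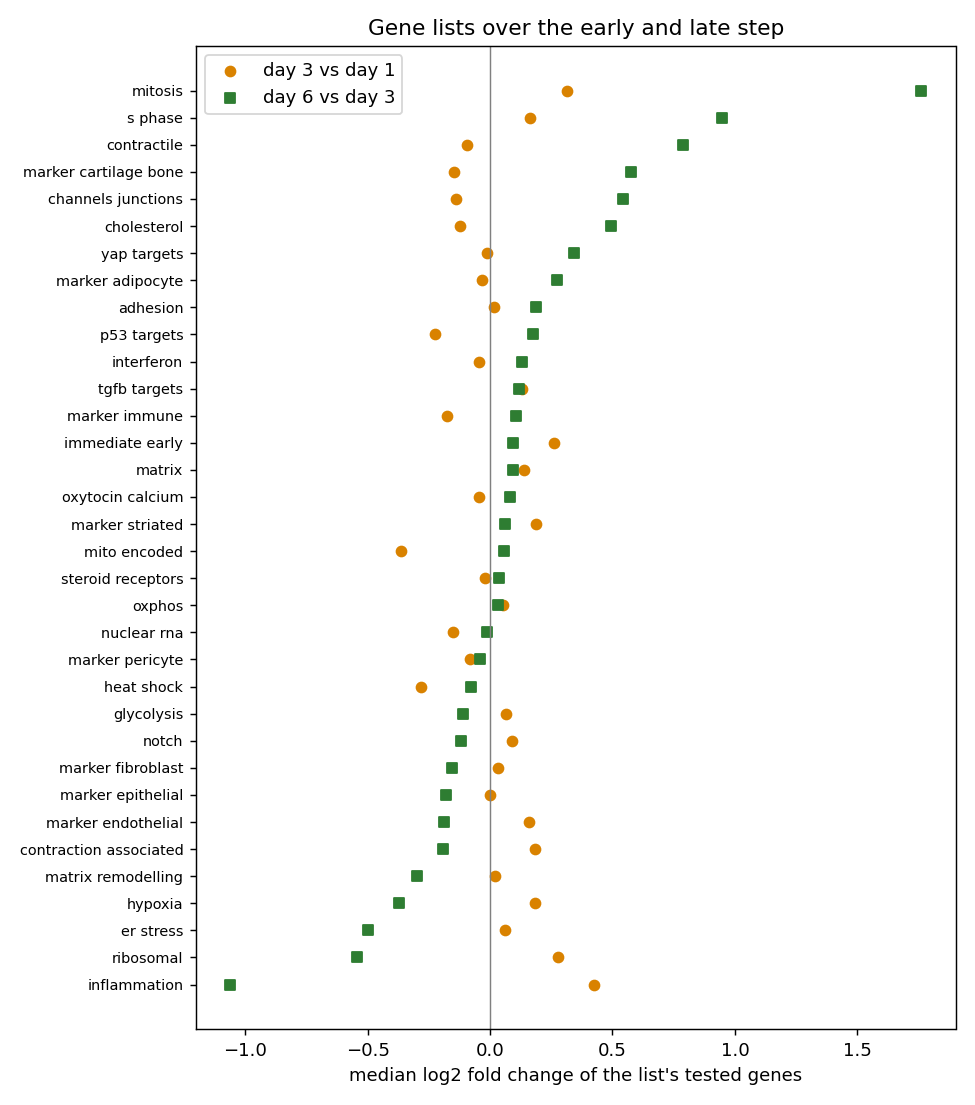
Median log2 fold change (horizontal axis) of the tested genes of each of the 34 lists (vertical axis, ordered by the late step); circles are day 3 against day 1 and squares day 6 against day 3. The mitosis list has medians of 0.316 and 1.76, and the inflammation list 0.424 and -1.06. With library totals only, late-step medians of the glycolysis, heat shock, notch, nuclear RNA and the endothelial, epithelial, fibroblast and pericyte marker lists were above 0, and early-step medians of matrix remodelling, adhesion, oxphos and the epithelial and fibroblast marker lists below 0.

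The day 6 against day 1 comparison spans the whole formation. ACTA2 was higher by 2.29 on the log2 scale (SE 0.141, adjusted p = 3.66e-07, edgeR), ACTG2, the enteric smooth muscle actin, by 2.10 (SE 0.148), and CNN1 by 1.62 (SE 0.0946). TAGLN and MYLK were higher by 1.45 and 1.02, and PTGS2 had a log2 change of -0.84. OXTR rose by 0.65 (SE 0.154, adjusted p = 0.0026, edgeR), and GJA1 had a log2 change of 0.33 that was not called (adjusted p = 0.0567, edgeR). MYH11, smooth muscle myosin heavy chain, was at 1.14 ± 0.0921 and 1.551 ± 0.296 CPM (adjusted p = 0.126, edgeR). MKI67 rose by 2.62 (SE 0.27, adjusted p = 4.09e-05, edgeR) and COL1A1, a chain of type I collagen, from 2834 ± 578 to 5771 ± 1290 CPM. MMP1 had a log2 change of -3.92 (SE 0.205), IL36RN of -2.61 and GDF15, a stress-induced cytokine, of -2.18.

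Of 25 contractile genes 19 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 4.7e-08 and adjusted p = 0.449 with an estimated correlation), and all 34 mitosis genes rose (34 adjusted over the list alone, camera adjusted p = 3.09e-21 and adjusted p = 0.449 with an estimated correlation). Of 35 matrix genes 18 rose and 4 fell (18 and 6 adjusted over the list alone, camera adjusted p = 0.0116 and adjusted p = 0.761 with an estimated correlation), VCAN and POSTN, periostin, among the former and DCN, decorin, among the latter. The adhesion list was higher, with 18 of 30 genes risen and 4 fallen (19 and 4 adjusted over the list alone, camera adjusted p = 0.00186 and adjusted p = 0.666 with an estimated correlation). The heat shock list was lower, with 10 of 14 fallen and 1 risen (12 and 1 adjusted over the list alone, camera adjusted p = 6.45e-05 and adjusted p = 0.449 with an estimated correlation). Ribosomal protein genes fell in 28 of 36 cases (33 adjusted over the list alone, camera adjusted p = 1.05e-10 and adjusted p = 0.666 with an estimated correlation). S phase genes rose in 33 of 35 cases (33 adjusted over the list alone, camera adjusted p = 1.72e-14 and adjusted p = 0.449 with an estimated correlation). Inflammation genes fell in 20 of 27 cases and rose in 6 (20 and 6 adjusted over the list alone, camera adjusted p = 6.45e-05 and adjusted p = 0.666 with an estimated correlation). Endoplasmic reticulum stress genes fell in 19 of 24 cases and rose in 3 (19 and 3 adjusted over the list alone, camera adjusted p = 5.17e-07 and adjusted p = 0.609 with an estimated correlation), SLC7A11 with -1.61. Cholesterol genes rose in 17 of 23 cases and fell in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 0.00125 and adjusted p = 0.761 with an estimated correlation). Of 21 YAP targets 9 rose (9 adjusted over the list alone, camera adjusted p = 0.018 and adjusted p = 0.666 with an estimated correlation), CCN2 by 1.17. Of 23 hypoxia genes 11 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.0179 and adjusted p = 0.761 with an estimated correlation). Of 34 matrix remodelling genes 14 fell and 7 rose (14 and 7 adjusted over the list alone, camera adjusted p = 0.0268 and adjusted p = 0.761 with an estimated correlation). Mitochondrially encoded genes fell in 5 of 13 cases (5 adjusted over the list alone, camera adjusted p = 0.0099 and adjusted p = 0.761 with an estimated correlation). Their share of counts on day 6 was 2.881% ± 0.661, with no difference detected from day 1 (exact permutation p = 0.429, adjusted 0.429) or day 3 (exact permutation p = 0.371, adjusted 0.417). Of 7287 called genes 3882 were higher and 3405 lower; library totals gave 5966 and 2040. Camera called 14 lists, and 3 of the 35 splits, the real one included, gave as many. The others that did so also kept most libraries of each day together. The splits therefore cannot decide whether chance gives this number either.

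The late step was compared with the early step directly, and 6423 genes differed. The contrast made no allowance for the late step being longer than the early step. A gene that changed at a constant daily rate could therefore also differ. Both steps were called for 1721 genes, and 1531 of them (89%) went in opposite directions, 851 up then down and 680 down then up, against 294.2 and 284.8 for independent lists. In 20 simulations of unchanged groups sharing the day 3 libraries the highest number of genes called in both steps was 1. No gene changed in these simulations, so few calls could arise in either step. That number therefore does not show how sharing acts on genes that do change. With the day 3 libraries split between the steps, the opposite share was 88.3% to 92.2% over 6 splits. The correlation of fold changes between the steps was -0.421 across genes, which are not independent replicates, and averaged -0.477 in those simulations, so a correlation of this size also arises from the shared libraries alone. With the day 3 libraries split it was -0.318 to -0.288. The covariance was -0.091, against a mean of -0.0189 in the simulations and -0.0757 to -0.0705 in the splits. Without day 1 replicate 1 or 2 the count called in both steps was 1006 and 976. PTGES, SLC7A2, MMP10, RASD1 and C11orf96 were highest on day 3, and VIPR1, SAA1, SAA2, S100A9 and JPH2, which encodes junctophilin 2, lowest.

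**Figure D4:**
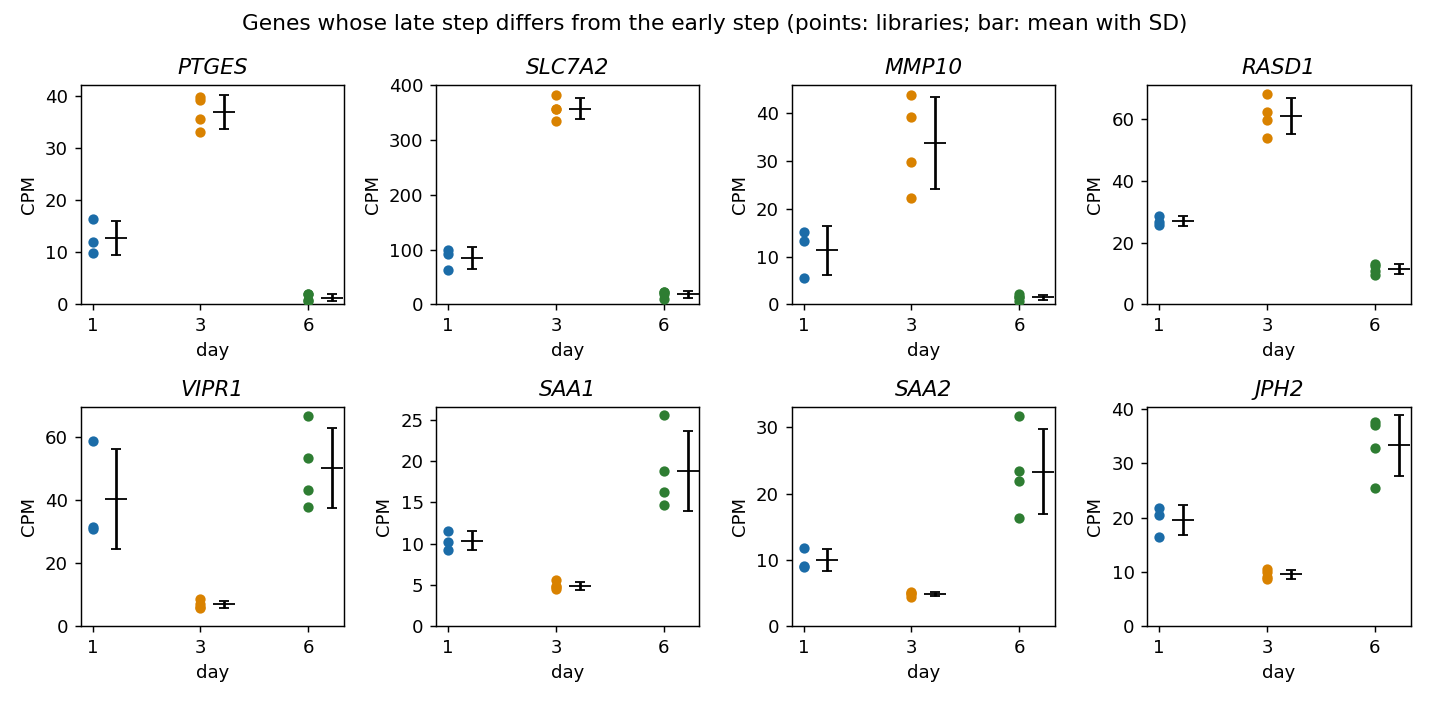
CPM (vertical axis, from 0) by day (horizontal axis) of 8 genes whose late step differed from the early step; points are libraries and bars give the mean with its SD. SLC7A2 was at 84.61, 357.7 and 18.81 CPM on days 1, 3 and 6, and VIPR1 at 40.38, 6.923 and 50.23 CPM.

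On GRCh38 the main genes lie as follows in the deposited table. ACTA2 (ENSG00000107796) spans positions 88934822 to 88991339 of chromosome 10, and OXTR (ENSG00000180914) spans 8750381 to 8769628 of chromosome 3. PTGES (ENSG00000148344) spans 129738331 to 129753042 of chromosome 9, SLC7A2 (ENSG00000003989) 17497088 to 17570573 of chromosome 8, and MKI67 (ENSG00000148773) 128096659 to 128126423 of chromosome 10. All are annotated as protein coding.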

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

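The tests of scaling, of short transcripts and of actin cytoskeleton genes in the closing section were chosen after the values had been seen; the splits of libraries, the length and GC test and the split of day 3 libraries were chosen before.

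The real grouping was set against other splits of the libraries. For day 3 against day 1, 1 of 35 splits, the real one, gave as many genes (2332, highest other 0). For day 6 against day 3 it was also 1 of 35 (9102, highest other 0). For day 6 against day 1 it was 1 of 35 as well (7287, highest other 2291). A split that mixes days adds the differences between days to the spread, which lowers its count. The splits also sample no new cultures, so they do not exclude chance differences between cultures. The same holds for the 6423 genes whose late step differed (1 of 100; highest other 824) and the 1721 called in both steps (1 of 100; highest other 0). For the number of lists called, 1 of 35 splits reached the real 13 for day 3 against day 1, with 12 the highest other. For day 6 against day 3, 12 of 35 splits reached the real 10 and the highest other was 13. For day 6 against day 1, 3 of 35 reached the real 14 and the highest other was 14. For those 2 list counts other splits did as well, but each of these kept most libraries of each day together. They still held part of the day difference, so they cannot decide whether chance gives as many list calls.

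The late and early steps differed by a test of the difference itself for 6423 genes, with no allowance for the unequal length of the steps. Among the named genes the late minus early difference was -6.33 for SLC7A2, -6.33 for PTGES (-6.327), -6.10 for MMP10, -3.73 for C11orf96 and -3.59 for RASD1, and 5.41 for VIPR1, 5.01 for S100A9, 3.28 for SAA2, 3.01 for SAA1 and 2.83 for JPH2. As a technical explanation, the shared day 3 libraries were split between the steps, and the lowest opposite share over 6 splits was still 88.3%, which argues against sharing as the whole cause. A change in culture or handling on the day 3 samples alone was not recorded and stays open, as does a biological difference between days.

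All 36 ribosomal protein genes fell from day 3 to day 6. After the trend on transcript length and GC content of the other genes was removed, the median residual was -0.611 (bootstrap 95% interval over genes -0.701 to -0.569). This argues against that trend, taken on the longest annotated transcripts, as the cause. The interval resamples genes with an estimated correlation of 0.691 and measures no spread between libraries. The higher of the medians under RLE factors and library totals was -0.358, which argues against scaling. A biological difference between the days was not tested further and stays open.

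MT-ATP8 fell more than MT-ATP6 from day 1 to day 3, with log2 changes of -1.74 and -0.50. A lower yield of short transcripts was tested on 167 other genes with a longest transcript of at most 300 nt. Their median log2 change was -0.0418 (bootstrap 95% interval over genes -0.134 to 0.0341), which argues against a lower yield of those genes as a group. Whether MT-ATP8 RNA behaves as a separate short transcript was not tested, so the values do not decide the question for MT-ATP8. The genes overlap on the mitochondrial genome, and how reads in the overlap were counted is not recorded, so that stays open.

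A single library lay apart from the other 3 of its day in 30 of 456 groups tested, where chance gives 22.8. Of these groups 29 are named here. The test took the gap to the nearest library as a share of the range of all 4. It therefore also picks small differences where the other 3 libraries agree closely. DNAJA1 on day 6 was at 285.5 CPM in 1 library and 298.6 to 299.7 CPM in the others. The difference was larger for S100A9 on day 6, at 10.59 CPM against 4.042 to 4.788 CPM. On day 3, replicate 1 was low for CNN1 (18.69 CPM) and high for MYOF (142.1), HCN2 (9.083), VEGFA (588) and PKM (1742). Replicate 2 was high for CCN1 (382.3), IRF7 (16.13) and RPS16 (659), replicate 3 low for CRYAB (1.197), and replicate 4 high for CENPF (8.481) and HMMR (2.471). On day 6, replicate 3 was low for SCG2 (3.368 CPM), DCN (1655), PXN (94.46), GREM1 (1341), JAG1 (9.345), HCN2 (4.612) and ABCC9 (2.579), and high for S100A9 (10.59). Replicate 4 was high for IL36RN (4.298) and PTGS2 (2498) and low for COL10A1 (8.295) and POSTN (63.7). Replicate 2 was low for BMP4 (10.39) and DNAJA1 (285.5) and high for ITGA6 (44.81) and EGFL7 (4.6), and replicate 1 was high for BGN (1333). IBSP in day 6 replicate 2 (0.0313) is 1 count against 0 in the others, below the limit of 3 counts, so that library is not shown to differ.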

How the results depend on the processing

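The alternatives were listed before the data were examined. With an added log2 fold change threshold of 1 the counts were 236, 1647 and 1277 for day 3 against day 1, day 6 against day 3 and day 6 against day 1, 2160 for the late minus early difference and 120 for both steps, fewer by construction. With only the 2 days compared, day 3 against day 1 gave 3617 genes. The spread between replicates was unequal. Pairs had a chi-square per degree of freedom of 7.145 to 16.7 on day 1 and 3.886 to 7.397 on day 3. On day 6 it was 14.72 to 29.81. The main fit shares its estimate of the spread over all days, and whether that lowered the early count was not tested. Leaving out each library gave 1344 to 2998 genes for day 3 against day 1 and 976 to 2112 for both steps, the highest of either without day 6 replicate 3. The cause was not tested. With an estimated correlation 0 lists were called in each comparison, and fry called 8 for day 3 against day 1 and 20 for day 6 against day 3. The other alternatives left these counts within 1.5 times, but single list calls ended. As few as 9 lists were called for day 3 against day 1, where the main analysis called 13. Apart from the estimated correlation and fry, calls ended in at least 1 alternative for the TGF-beta, S phase, hypoxia, cholesterol, matrix and mitosis lists in that comparison. They also ended for matrix remodelling in both comparisons with day 6, and for matrix, hypoxia and YAP targets for day 6 against day 1. Fry also ended those of the mitochondrially encoded list in both comparisons with day 1 and of the immediate early list for day 3 against day 1. The replicate block gave 2191, 9162 and 7119 genes in the comparisons of days, against 2332, 9102 and 7287 without it. Same-numbered libraries correlated at -0.0226 to 0.103, with 1 of 10 pairs over 0.1, and 7 of 11 libraries correlated best with their own number; same-lettered libraries correlated at -0.0833 to 0.0221. Not every same-numbered pair passed 0.1, so neither label was taken to pair the libraries, and the 7 of 11 is a hint from the data only.

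A sign change of a gene, or of a list's test direction, occurred for 55 values of 20 results, of which 0 were called in the main analysis and 0 under the alternative. Their cause was not tested. Lists were not tested with library totals only, DESeq2, limma-voom, no filter, thinning or only the 2 days compared. Sign changes of lists under those settings are therefore not counted. List values are medians, which can keep their sign where the test's direction turned. OXTR for day 3 against day 1 was -0.021 with library totals only and -0.08 to 0.22 leaving out libraries, MYH11 -0.22 to 0.071 and PTGS2 -0.0075 to 0.45. The stricter filter gave the notch list -0.077 and the fibroblast markers -0.069 for day 3 against day 1, and the notch list 0.18, the mitochondrially encoded list 0.063 and the adipocyte markers 0.57 for day 6 against day 3. Under the letter block, day 6 against day 3 gave steroid receptors 0.018, oxphos 0.048, mitochondrially encoded 0.088 and immediate early -0.036. Fry turned notch (0.091) for day 3 against day 1, mitochondrially encoded (0.055), immediate early (0.092) and adipocyte (0.27) for day 6 against day 3, and pericyte (-0.12) for day 6 against day 1; the replicate block gave oxytocin and calcium -0.030 there. Leaving out libraries, the medians for day 3 against day 1 were -0.018 to 0.12 for glycolysis, -0.094 to 0.056 for interferon, -0.065 to 0.095 for fibroblast, 0.050 to 0.16 for notch and -0.038 to 0.016 for steroid receptors. For day 6 against day 3 they were 0.023 to 0.19 for immediate early, -0.26 to 0.31 for immune, -0.097 to 0.14 for mitochondrially encoded, -0.026 to 0.052 for oxphos, 0.016 to 0.074 for steroid receptors and 0.044 to 0.13 for TGF-beta targets. In the comparison of days 1 and 6 they were -0.18 to -0.0046 for pericyte, -0.047 to 0.064 for notch, -0.062 to -0.0062 for oxytocin and calcium and 0.0066 to 0.12 for steroid receptors.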

Other observations

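The 8 gene lists of this part were written after the data had been seen, so their tests are not independent evidence. Of 8 metallothionein and zinc transporter genes 6 rose from day 1 to day 3 and all 8 fell from day 3 to day 6 (camera adjusted p = 1e-05 and 2.95e-05, or adjusted p = 0.0275 and 0.0539 with an estimated correlation). MT1X, a metal-binding protein, had log2 changes of 0.55 and -0.99. Of 15 amino acid transporter genes 10 fell and 1 rose in the late step (camera adjusted p = 2.08e-05 and adjusted p = 0.0539 with an estimated correlation), SLC7A5 with a log2 change of -2.14. Of 10 lipid droplet and peroxisome proliferator-activated receptor target genes 8 fell (camera adjusted p = 2.6e-05 and adjusted p = 0.0539 with an estimated correlation), PLIN2 with -2.26. Of 22 translation factor genes 19 fell and 1 rose (camera adjusted p = 3.24e-09 and adjusted p = 0.0691 with an estimated correlation). The one that rose, EIF4A1, had a mean of 2.199 CPM, the lowest of that list. Of 7 acute phase genes 6 rose (camera adjusted p = 0.00515 and adjusted p = 0.0691 with an estimated correlation). In the early step 4 of the 7 acute phase genes fell and 0 rose, with a median log2 change of -1.07 (camera adjusted p = 1.95e-05 and adjusted p = 0.0275 with an estimated correlation), and day 6 against day 1 was not called (camera adjusted p = 0.516 and adjusted p = 0.65 with an estimated correlation). The hyaluronan and clock lists were not called in the late step (camera adjusted p = 0.464 and 0.883).

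A hypothesis was that the rise of contractile genes on day 6 may be part of a wider change in actin cytoskeleton genes that the SRF transcription factor regulates. The median log2 change, day 6 against day 3, of 20 such genes outside the contractile list was 0.48 (bootstrap 95% interval over genes 0.338 to 0.685). Of these genes 19 rose and 1 fell (camera adjusted p = 3.33e-08 and adjusted p = 0.0539 with an estimated correlation, so the list is not called there). In the early step 10 of the 20 fell and 0 rose (median -0.19, camera adjusted p = 5.39e-05 and adjusted p = 0.161 with an estimated correlation), and the contractile list had a median of -0.10 and was not called (camera adjusted p = 0.119 and adjusted p = 0.78 with an estimated correlation). The late step goes with the hypothesis, but the list was written after the values had been seen and is no independent test. The early step leaves the hypothesis open. The activity of SRF was not measured, and the SRF gene is itself a member of the contractile list. FLNA, ACTN1 and ZYX are also on the adhesion list.

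None of the 8 lists of markers of other cell types was called by camera in the late step. The camera adjusted p was 0.334 for endothelial, 0.526 for epithelial, 0.973 for immune, 0.834 for fibroblast, 0.834 for pericyte, 0.58 for cartilage and bone, 0.973 for adipocyte and 0.907 for striated muscle markers, and 3 of 15 immune markers passed the filter. The fry test called 4 of the lists, endothelial (adjusted p = 0.000477) and epithelial (0.000757) lower and pericyte (0.014) and cartilage and bone (0.0488) higher, with medians of -0.19, -0.18, -0.04 and 0.57. Fry asks whether a list changed at all and camera whether it changed more than other genes. With an estimated correlation camera gave adjusted p = 0.539, 0.716, 0.928 and 0.884, and with library totals the endothelial and epithelial medians were 0.000523 and 0.00532. CXCL8 took 1.761% ± 0.294, 2.465% ± 0.152 and 1.279% ± 0.254 of counts on days 1, 3 and 6. TERT, the gene used to immortalise the line, was at 1154 ± 121, 1065 ± 95.4 and 1075 ± 210 CPM. The nuclear RNA MALAT1 had 0 to 7 counts per library, while NEAT1 had 3332 to 12524. How reads in regions where genes overlap were counted is not given in the sources used here, so the MALAT1 counts do not show that the RNA was absent.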
